A study of Homo sapiens with 10 samples.

How the data were processed

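RNA from the human melanoma line MNT-1, a heavily pigmented line, was measured on 10 arrays of the type the labels spell Clarion S Human. The cells had been kept in serum-depleted medium for 48 h. They then received 20 uM forskolin, an activator of adenylyl cyclase that raises cyclic AMP, for 30 min, after which the medium was replaced. RNA was taken before forskolin (0 h) and at 4, 7, 11, 15, 19, 23, 27, 33 and 39 h. Each time point has 1 array, so no time point has a replicate, and no unstimulated array was taken at a later time. Time since forskolin and time since the start of serum depletion therefore advance together in every array. The 0 h array was taken before the pulse, so the change of medium also separates it from every stimulated array.

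The deposited values are log2 signals that the authors made with RMA (background correction, quantile normalization and a summary over the probes of each transcript cluster), per the submitters' processing notes. The genome build is not given in the sources used here, and no coordinates are printed. The table held 19577 probe sets, of which 17709 carried 1 gene symbol through their Entrez identifiers and 1868 carried none. For the 20 genes with more than 1 probe set the one with the highest mean was kept, which left 17687 genes. No filter on dim signals was applied and no further normalization was made. The number of arrays limits the precision of every value.

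The 9 stimulated arrays were grouped into an early window (4, 7 and 11 h), a middle window (15, 19 and 23 h) and a late window (27, 33 and 39 h), and the unstimulated array stood alone. Models were fitted with limma 3.58.1 in R 4.3.3, with variances moderated along a trend on mean signal, Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Change over time was tested with a natural cubic spline of 3 degrees of freedom (splines 4.3.3) over all 10 arrays, which left 6 residual degrees of freedom. For each gene the largest departure of the fitted curve from its value at 0 h gave the direction and the size. Differences between windows came from a model with 4 means and 6 residual degrees of freedom. A rhythm of 24 h was tested with a sine and a cosine beside a linear term on the 9 stimulated arrays, with 5 residual degrees of freedom. The p-values measure the spread around a smooth curve or within a window, and the single unstimulated array was assumed to vary as the windows do. The comparisons with the unstimulated array share its error.

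The grouping, the tests, the 26 gene lists, the rule for named genes and most of the alternatives were chosen before the data were examined. The lists covered pigmentation, melanocyte transcription factors, MITF targets outside pigmentation, CREB immediate targets, the circadian clock, hypoxia, DNA replication, mitosis, DNA repair, p53 targets, cholesterol synthesis, the ATF4 amino acid response, ER chaperones, oxidative phosphorylation, lysosome, inflammatory signalling, interferon, MAPK output, dedifferentiation and invasion, oxidative stress, heat shock, ribosomal proteins, reference genes, and markers of keratinocytes, of fibroblasts and of immune and endothelial cells. Of their 512 members 443 were measured. Each list was tested against the other genes in the 4 window contrasts with camera of limma at a preset correlation of 0.01, adjusted over the 104 tests, and again with the correlation estimated from the data. Its median was set beside 10000 random lists of the same size and signal level. The named genes were MITF, the 10 largest rises and 10 largest falls of the spline test, the 8 highest and 8 lowest differences of each window contrast, and up to 4 members of each described list with the smallest adjusted p in the spline test. ACTB, GAPDH and TBP are given as values. Other genes are named where the text says that they were chosen after their values were seen. Members of a list past the threshold in a window contrast are named as examples of its count.

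The models were tested on simulated data with 67 or 66 changed genes per size. For a smooth hump the spline test recovered 2.99%, 58.2% and 100% of the genes at log2 changes of 0.5, 1 and 2, and for a steady trend 5.97%, 47.8% and 93.9%. The early window against the unstimulated array recovered 1.49%, 49.3% and 93.9%, the late against the early window 23.9%, 85.1% and 100%, and the rhythm test 53.7%, 100% and 98.5% of amplitudes of 0.5, 1 and 2. Between 1 and 6 unchanged genes were called in each run. A list shifted by 0.3 was called in 2 of 2 tests, with 0 calls in the other 102. The simulated genes varied independently, so this run does not show how often lists with correlated members are called by chance. Differences that many genes share between arrays were not simulated either, so the recovered shares may be too high for the data. In the data the estimated correlation was 0.454 for DNA replication and 0.495 for mitosis genes. As 49.3% of the simulated changes of 1 against the unstimulated array were recovered, changes of about 1 or less on the log2 scale would often be missed there.

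The alternatives covered normalization, a filter on the 40% of genes with the lowest mean, moderation, the probe set per gene, the shape of the curve, the windows, the period of the rhythm, the list test and the omission of each array in turn. List tests after quantile normalization or median centring, and the shifted middle window, were added after the data had been seen. Figures were drawn in Python 3.11.15. The 1868 probe sets without a symbol were tested separately and are not named.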

Results

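The data follow MNT-1 melanoma cells for 39 h after a forskolin pulse of 30 min, with 1 array per time point. There was 1 unstimulated array, and the early, middle and late windows held 3 arrays each. The series concerns a timer in skin protection against ultraviolet light, and forskolin stands in for the cyclic AMP signal that sun exposure sets off in pigment cells. The array medians ran from 6.18 at 11 h to 6.27 at 39 h on the log2 scale, and the standard deviation of the signals was 1.99 at 39 h and 2.04 to 2.07 in the other arrays. GAPDH, a glycolytic enzyme often used as a reference, measured 13.07 at 0 h and 13.02 ± 0.07 (SD, n = 3) in the late window. The cytoskeletal actin ACTB measured 9.25 and 9.51 ± 0.21, and the TATA-binding protein TBP 8.31 and 8.52 ± 0.09. None of the 3 passed the test for change over time, with adjusted p-values of 0.773, 0.182 and 0.522, and GAPDH lay so close to the highest signal of any probe set (13.18) that its steady level carries little weight.

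The arrays did not change at an even pace. Between 11 and 15 h 199 genes differed more than 2-fold, and between 33 and 39 h 152 did, while the other neighbouring pairs differed at 6 to 79 genes, the last of these between 0 and 4 h. The first principal component held 30.0% of the variance and the second 20.2%. The smallest mean absolute difference between any pair of arrays was 0.177, so no pair held the same measurement.

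**Figure D1:**
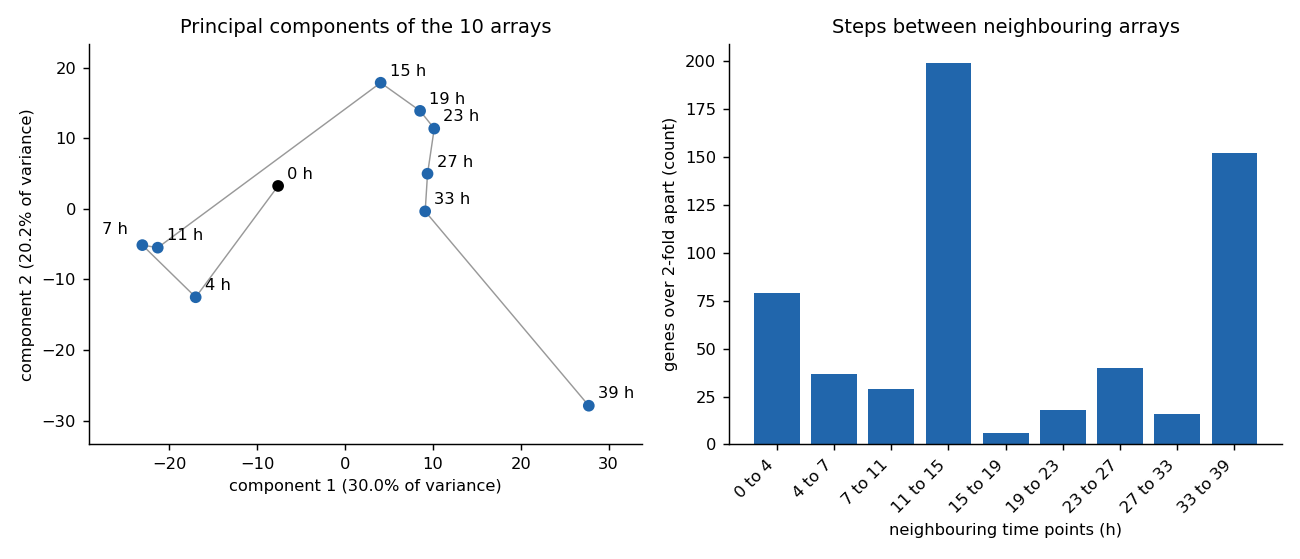
Position of the 10 arrays on the first 2 principal components (left, axes in percent of variance) and number of genes more than 2-fold apart between neighbouring time points (right, bars). The bars for 11 to 15 h (199 genes) and 33 to 39 h (152 genes) are the highest.

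MITF, the master transcription factor of the pigment cell lineage, was among the strongest signals on the arrays, ranking 31 by mean. Its level was 12.19 at 0 h, 12.32 ± 0.14 (SD, n = 3) in the early, 12.10 ± 0.04 in the middle and 12.09 ± 0.08 in the late window. The highest value was 12.41 at 4 h and the lowest 12.02 at 33 h, a range of 1.31-fold. Neither the spline test (adjusted p = 0.359) nor the late against the early window (-0.23, SE 0.08, adjusted p = 0.0609) passed. The highest signal of any probe set was 13.18, so MITF lay near the top of the range of the arrays, where signals can be compressed and the fold range can understate a change.

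Over the whole course, the question was which genes followed a smooth curve away from its fitted value at 0 h. PNLIPRP3, a relative of the pancreatic lipases, rose 5.07-fold on the fitted curve by 23 h (adjusted p = 0.00153), from 4.17 at 0 h to 6.53 ± 0.22 (SD, n = 3) in the middle window. Its 0 h level was as low as the marker lists of other cell types (median 3.92 for keratinocytes and 4.78 for fibroblasts). It was not shown to lie above background, so the fold is uncertain. CDKN1A, which encodes the cell cycle inhibitor p21, rose 3.73-fold by 39 h (adjusted p = 0.000701) and stood at 7.86 ± 0.80 in the late window against 6.80 at 0 h. ID2, an inhibitor of basic helix-loop-helix transcription factors, fell along the curve to a log2 change of -2.27 at 39 h (adjusted p = 0.00669), from 8.25 at 0 h to 6.38 ± 0.59 in the late window. CCNE2, a cyclin of the entry into DNA synthesis, reached -1.89 on the fitted curve at 27 h (adjusted p = 0.0318), where the measured difference from the unstimulated array was -1.08. RPS6KA5, a kinase that phosphorylates CREB and histone H3, reached -1.81 on the curve at 27 h (adjusted p = 0.0199), where the measured difference was -0.98, after an early window mean 0.84 above the unstimulated array (adjusted p = 0.148, not past the threshold).

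The other named rises were RHOQ-AS1 (log2 change 1.95 at 39 h), the myosin gene MYO16 (1.86 at 15 h), THSD7A (1.82 at 23 h), ENTHD1 (1.81 at 23 h), RFTN2 (1.68 at 33 h), the Wnt modulator DKK2 (1.60 at 15 h), GDPD1 (1.46 at 27 h) and CFAP61 (1.44 at 15 h). RHOQ-AS1 measured 3.86 at 0 h, also not shown to lie above background, so the size of its rise is uncertain. MYO16 (4.86) and DKK2 (4.78) were near the levels of those marker lists at 0 h as well. The other named falls were MUC7 (-1.84 at 23 h), OMG (-1.75 at 27 h), the fatty acid elongase ELOVL4 (-1.65 at 39 h), the sodium-proton exchanger SLC9A2 (-1.59 at 15 h), the mitochondrial GTPase NOA1 (-1.56 at 39 h), the complex I assembly factor NDUFAF6 (-1.55 at 39 h) and the GABA receptor subunit GABRA3 (-1.55 at 27 h). Low levels near those of the marker lists were reached by SLC9A2 (3.94 in the middle window), MUC7 (4.27), OMG (4.71) and ELOVL4 (4.29 at 39 h). The sizes for these genes, MYO16 and DKK2 are therefore uncertain, here and in the window contrasts below. The sizes given above are those of the fitted curve, and the measured differences at the same times were smaller by more than 1.5 times for GDPD1 (0.96) and MUC7 (-1.22). Of the 20 named genes 10 passed whichever array was left out: PNLIPRP3, RHOQ-AS1, CDKN1A, MYO16, THSD7A, ENTHD1, ID2, MUC7, OMG and GABRA3. Leaving out the 39 h array took CDKN1A to 0.90 and ended the calls of NOA1 (-0.57), NDUFAF6 (-0.71), ELOVL4 (-0.46) and RFTN2 (1.53). Leaving out the unstimulated array took MYO16 to 0.87 and ended the calls of CFAP61 (0.39), DKK2 (0.48) and SLC9A2 (-0.57). These sizes are counted from the fitted value at 4 h, so they are not on the same baseline as the others. Without the 4 h array GDPD1 (adjusted p = 0.0813), RPS6KA5 (0.0989), RFTN2 (0.139), CCNE2 (0.119), DKK2 (0.0853), CFAP61 (0.066) and ELOVL4 (0.0538) did not pass. Without the 7 h array GDPD1 (0.0844), RPS6KA5 (0.0855), RFTN2 (0.0691), CCNE2 (0.0763), DKK2 (0.0873) and ELOVL4 (0.0593) did not. CCNE2 also lost its call without the 19 h (0.0616) or the 23 h array (0.0602), DKK2 without the 11 h array (0.0711), and RFTN2 without the 11, 19, 23 or 33 h array (0.0511, 0.0767, 0.0668 and 0.0539). With a curve of 4 degrees of freedom the largest departure of GDPD1 was -1.09.

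In all, 861 of 17687 genes passed the spline test, of which 304 rose and 557 fell, and 4126 had an unadjusted p under 0.05. Rises and falls are counted from the fitted value at 0 h, which can lie away from the measured one. PHEX counts as a fall (-1.22 at 27 h), though its measured difference from 0 h there was -0.10. STEAP2 counts as a rise (0.88 at 27 h), with a measured difference of 0.09. For 112 of the rises and 370 of the falls the largest departure was at the 39 h array, which stands apart from the others. Without that array 628 genes passed, 303 up and 325 down. The count was 222 without the 4 h array, 266 without the 7 h array, 361 without the 11 h array, 522 without the 19 h array, 1454 without the 15 h array and 1302 without the unstimulated array. It was 375 without the trend on mean signal, 2271 with a curve of 4 degrees of freedom and 496 with linear time.

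**Figure D2:**
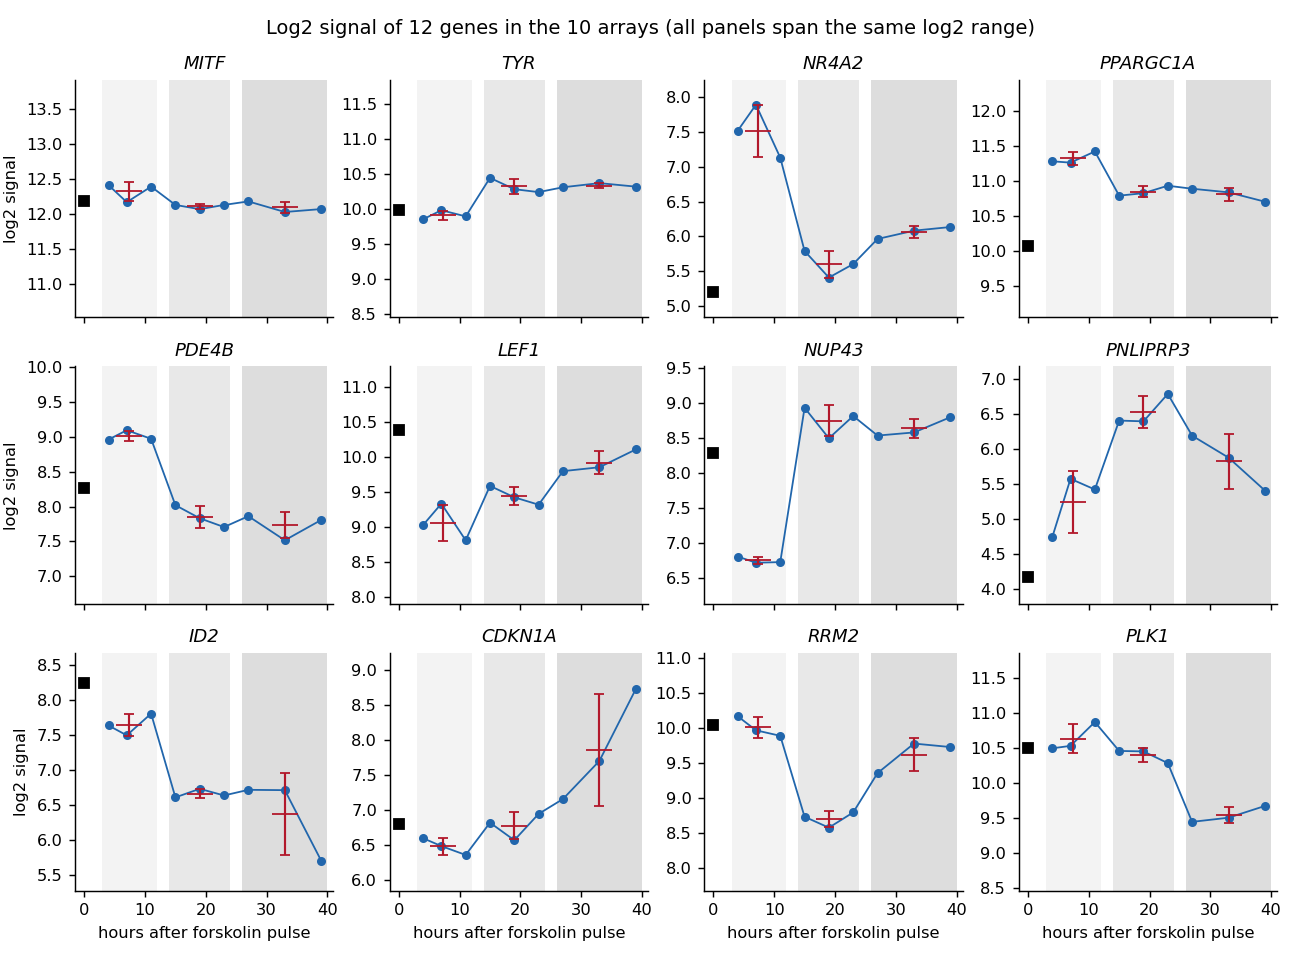
Log2 signal of 12 genes (vertical axes) against hours after forskolin (horizontal axes), with the unstimulated array as a black square, stimulated arrays as blue points, and the mean and SD of each window of 3 arrays in red. MITF stays between 12.02 and 12.41, while NR4A2 is 5.20 at 0 h and 7.51 in the early window.

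The early window was set against the unstimulated array to ask what differed in the first hours after cyclic AMP rose. NR4A2, an orphan nuclear receptor gene that CREB switches on, was 2.31 higher on the log2 scale (SE 0.26, adjusted p = 0.00022), from 5.20 to 7.51 ± 0.38 (SD, n = 3). MEF2C, a transcription factor of muscle, nerve and neural crest cells, was 1.95 higher (SE 0.39) and PHEX, a membrane endopeptidase, 1.76 higher (SE 0.26). LEF1, the nuclear partner of beta-catenin in Wnt signalling, was lower by -1.33 (SE 0.18, adjusted p = 0.0017), from 10.38 to 9.05 ± 0.26, and PTCH1, the receptor of hedgehog, was lower by -1.35 (SE 0.20). NUP43, a part of the nuclear pore, was lower by -1.54 (SE 0.19, adjusted p = 0.00055), from 8.29 to 6.75 ± 0.05.

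CDH19 (1.69), SLAIN1 (1.57), the lysophosphatidic acid receptor LPAR6 (1.44), MYO16 (1.42) and the secreted glycoprotein STC1 (1.40) made up the other high values. STEAP2 (8.77 at 0 h, 7.27 ± 0.39 early), RUBCNL (-1.45), the receptor phosphatase PTPRZ1 (-1.33), SLC9A2 (-1.33) and DNAI3 (-1.32) made up the other low values. PHEX at 0 h (4.67), and PTPRZ1 (4.37), DNAI3 (4.53) and RUBCNL (4.70) in the early window, lay near the levels of the marker lists. The sizes of their differences are uncertain. In all, 84 genes passed, 35 higher and 49 lower, and 1413 had an unadjusted p under 0.05. Of the 16 named genes 10 passed whichever stimulated array was left out. The single unstimulated array, on which each of these calls rests, could not be left out. Without the 11 h array the calls of RUBCNL (-1.26), LPAR6 (1.34), SLAIN1 (1.43), DNAI3 (-1.26) and MYO16 (1.14) ended, and without the 7 h array those of MEF2C (1.79) and MYO16 (1.52). DNAI3 also lost its call without the 4 h or the 23 h array (adjusted p = 0.0906 and 0.0563) and MYO16 without the 15, 19, 23 or 33 h array (adjusted p = 0.0699, 0.0717, 0.0681 and 0.0548). The count was 52 without the 7 h array, 54 without the 11 h array and 170 without the 39 h array. With all 3 windows shifted (4 and 7 h, 11 to 19 h, and 23 to 39 h) limma called 0 genes, with 829 at an unadjusted p under 0.05, and without the trend on mean signal it called 25.

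CREB immediate targets, the genes that the cyclic AMP pathway reaches first, were higher as a list in the early window, with a median of 0.44 over 18 measured members (camera adjusted p = 8.6e-09; adjusted p = 0.0515 with an estimated correlation). NR4A2, NR4A3 (0.63, SE 0.12) and the mitochondrial coactivator PPARGC1A (1.25, SE 0.12, adjusted p = 3.8e-05) passed over all genes, 15 did not, and adjusted over the list alone 7 were higher and 1 lower. Between the early and the late window the list went down by a median of -0.40 (adjusted p = 4.1e-05; adjusted p = 0.119 with an estimated correlation). The phosphodiesterases PDE4B (-1.28, SE 0.13) and PDE4D (-1.10, SE 0.16), which break down cyclic AMP, and the phosphatase DUSP1 (-1.01, SE 0.16) were among 10 members that were lower, and PDE3B (0.53) was the 1 higher. PPARGC1A was still above the unstimulated level in the middle (0.77, adjusted p = 0.0034) and late windows (0.74, adjusted p = 0.0094). Of the 18 members 5 passed the spline test, all down from the fitted rather than the measured value at 0 h, among them EGR1 (-1.23 at 15 h). Adjusted over the list alone 5 rose and 6 fell.

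Oxidative stress genes, which keep glutathione and thioredoxin reduced, had a median of 0.23 in the early window over 15 members (adjusted p = 0.0019; adjusted p = 0.809 with an estimated correlation), with OSGIN1 (0.97, SE 0.17) the 1 member past the threshold and 5 adjusted over the list alone. From the early to the late window the median was -0.31 (adjusted p = 0.001; adjusted p = 0.809 with an estimated correlation), or -0.18 without the 39 h array. GCLM (-1.63, SE 0.22) and GCLC (-1.20), the subunits of the enzyme that limits glutathione synthesis, were lower with OSGIN1 (-0.85), HMOX1 (-0.60), TXNRD1 (-0.40) and SLC7A11. The iron storage gene FTL (0.50) was higher and 8 members did not pass, while adjusted over the list alone 2 were higher and 8 lower. Of the 15 members 6 passed the spline test, 2 up and 4 down, and 9 adjusted over the list alone.

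The 13 measured heat shock genes, which encode chaperones, had a median of -0.34 in the early window (adjusted p = 8e-05; adjusted p = 0.308 with an estimated correlation) and of 0.24 in the middle window (adjusted p = 0.00037; adjusted p = 0.357 with an estimated correlation). CHORDC1 (-0.90, SE 0.14) was the member lower in the early window over all genes, and 6 were lower adjusted over the list alone. HSPA1A (0.93, SE 0.16) was the member higher in the middle window, and 2 were higher adjusted over the list alone. Between 11 and 15 h, where the arrays stepped apart, the list median went from -0.20 to 0.20. HSPB1 (0.78, adjusted p = 0.00017), CHORDC1 (0.74), FKBP4 (0.61) and HSPA1A (0.53) were higher in the late than in the early window, where the list median was 0.14 (adjusted p = 0.0059; adjusted p = 0.45 with an estimated correlation) and 6 passed adjusted over the list alone. That median was 0.29 without the 11 h array. CIRBP and RBM3, which cold induces and which were chosen after their values or those of the list were seen, differed the other way, from 9.09 ± 0.23 to 7.35 ± 0.16 and from 11.05 ± 0.10 to 10.58 ± 0.10 (SD, n = 3) between the early and the middle window. In the limma spline test 0 heat shock genes passed over all genes, 4 adjusted over the list alone and 7 had an unadjusted p under 0.05.

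The middle window against the unstimulated array asked what had moved by 15 to 23 h. PNLIPRP3 was 2.35 higher (SE 0.31, adjusted p = 0.0011) and FOSL2, a component of the transcription factor AP-1, 1.29 higher (SE 0.17, adjusted p = 0.0011). RRM2, the ribonucleotide reductase subunit that supplies deoxynucleotides, was lower by -1.35 (SE 0.17, adjusted p = 0.00072), CCNE2 by -1.74 (SE 0.25, adjusted p = 0.0022), ID2 by -1.59 (SE 0.29) and its relative ID3 by -1.36 (SE 0.22). THSD7A (1.91), ENTHD1 (1.82), MYO16 (1.80), CFAP61 (1.42), the presynaptic protein PCLO (1.31) and ST6GALNAC3 (1.24) were also higher, and OMG (-1.81), SLC9A2 (-1.81), the olfactory receptor OR7A5 (-1.51) and PLPPR4 (-1.47) also lower. In all, 83 genes passed, 30 higher and 53 lower, and 1548 had an unadjusted p under 0.05. Leaving out the 23 h array ended the calls of PCLO (1.24) and ST6GALNAC3 (1.15), as did the 15 h array for PCLO (1.19) and the 19 h array for ST6GALNAC3 (adjusted p = 0.0654). The other 14 named genes passed whichever stimulated array was left out. The count was 42 without the 19 h array, 52 without the 23 h array, 210 without the 39 h array, 25 without the trend on mean signal and 7 with all 3 windows shifted.

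DNA replication genes were lower in the middle window in 21 of 21 members, with a median of -0.80 (adjusted p = 2.5e-27; adjusted p = 0.281 with an estimated correlation). Over all genes 8 members passed, among them CCNE2, RRM2, the thymidylate synthase TYMS (-1.21, SE 0.17) and the sliding clamp PCNA (-0.95), 13 did not, and 18 passed adjusted over the list alone. The median difference from 0 h was -0.94 at 15 h, the first array after the step, and -0.23 at 33 h and -0.48 at 39 h. For the late window it was -0.37 (adjusted p = 8.9e-08; adjusted p = 0.809 with an estimated correlation), with 0 members past the limma threshold, 9 adjusted over the list alone and 11 with an unadjusted p under 0.05. From the early to the late window the median was -0.27 (adjusted p = 9.5e-05; adjusted p = 0.905 with an estimated correlation), with 5 members lower and 8 adjusted over the list alone, and -0.17 without the 39 h array. Along the fitted curve 4 members fell over all genes and 13 adjusted over the list alone.

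Mitosis genes reached their low point later. Their median was -0.20 in the middle window (adjusted p = 0.0106; adjusted p = 0.962 with an estimated correlation), a call that ended without the 19 h array (adjusted p = 0.0729), with 0 members past the limma threshold, 2 adjusted over the list alone and 3 with an unadjusted p under 0.05. In the late window it was -0.68 (adjusted p = 3.3e-17; adjusted p = 0.442 with an estimated correlation), 21 of 21 members were lower in value, 5 passed, among them the kinase PLK1 (-0.96, SE 0.15), the cyclins CCNB2 (-1.16) and CCNA2 (-0.94), and 14 passed adjusted over the list alone. From the early to the late window the median was -0.62 (adjusted p = 2.3e-15; adjusted p = 0.45 with an estimated correlation), and 13 members were lower, among them the motor KIF11 (-1.22), PLK1 (-1.09) and the kinase CDK1 (-1.05), with 18 adjusted over the list alone. The median difference from 0 h was 0.16 at 11 h, -0.17 at 23 h, -0.96 at 27 h and -0.48 at 39 h, and at 39 h 19 of 21 members were above their mean of 27 and 33 h. Over the whole course 8 members fell over all genes, and adjusted over the list alone 2 rose and 14 fell.

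**Figure D3:**
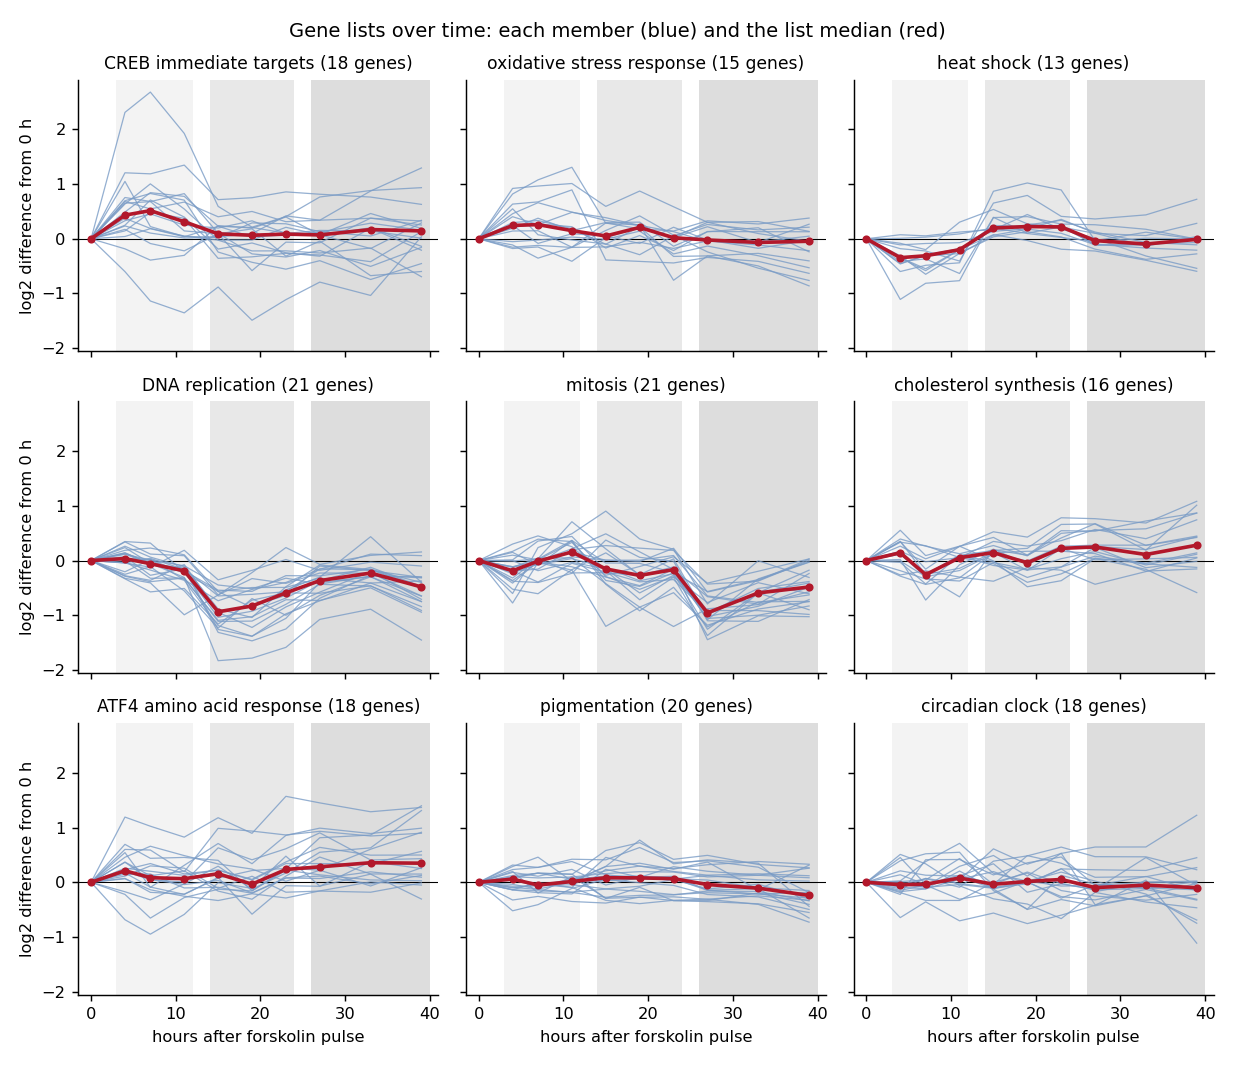
Log2 difference from the unstimulated array (vertical axes) against hours after forskolin (horizontal axes) for 9 gene lists, with each member in blue and the list median in red. The DNA replication median is lowest at 15 h (-0.94) and the mitosis median at 27 h (-0.96).

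The late window against the unstimulated array asked which differences were present after 27 h. STC1 was 1.44 higher (SE 0.24, adjusted p = 0.0099), DDIT3, the stress transcription factor CHOP, 1.37 higher (SE 0.23, adjusted p = 0.012), FOSL2 1.36 higher (SE 0.17, adjusted p = 0.0024) and SPRY1, an inhibitor of receptor tyrosine kinase signalling, 1.33 higher (SE 0.25). ID2 was lower by -1.87 (SE 0.29, adjusted p = 0.0079), the mitotic kinase PBK by -1.21 (SE 0.16, adjusted p = 0.0024) and FBXO5, an inhibitor of the anaphase-promoting complex, by -1.19 (SE 0.23). PNLIPRP3 (1.65), ENTHD1 (1.49), CFAP61 (1.27) and UBAP1L (1.17) were also higher, and OMG (-1.47), SLC9A2 (-1.45), GABRA3 (-1.40), the matrix protein MATN2 (-1.28) and CLEC2B (-1.18) also lower. In all, 48 genes passed, 18 higher and 30 lower, and 1833 had an unadjusted p under 0.05. Of the 16 named genes 9 passed whichever stimulated array was left out. Without the 27 h array PNLIPRP3 (adjusted p = 0.0568), CFAP61 (0.0627), SPRY1 (0.0528), UBAP1L (0.062), GABRA3 (0.0547), FBXO5 (0.0568) and CLEC2B (0.0568) did not pass, and without the 33 h array PNLIPRP3 (0.0645), CFAP61 (0.0764), UBAP1L (0.0863), GABRA3 (0.0717) and CLEC2B (0.067) did not. CFAP61 also lost its call without the 15, 19 or 23 h array (0.0501, 0.0538 and 0.0534) and UBAP1L without the 4, 7 or 19 h array (0.0505, 0.0632 and 0.0538). The count was 29 without the 27 h array and 80 without the 39 h array, 4 with all 3 windows shifted, 5 without the trend on mean signal and 83 with the dimmest 40% of genes left out.

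ATF4 targets, which respond to a lack of amino acids, had a median of 0.34 in the late window over 18 members (adjusted p = 2e-06; adjusted p = 0.45 with an estimated correlation), where DDIT3 passed and 9 members were higher adjusted over the list alone. In the middle window the median was 0.14 (adjusted p = 0.0442; adjusted p = 0.905 with an estimated correlation), with DDIT3 (1.22) and DDIT4 (0.93) past the threshold and 4 adjusted over the list alone. That call ended without the 15 h array (median 0.09, adjusted p = 0.114) or the 23 h array (median 0.10, adjusted p = 0.214), and, with the median still 0.14, without the 33 h (adjusted p = 0.0509) or the 39 h array (adjusted p = 0.055). From the early to the late window the median was 0.33 (adjusted p = 0.002; adjusted p = 0.895 with an estimated correlation). The pseudokinase TRIB3 (1.01, SE 0.18), the asparagine synthetase ASNS (0.70), CEBPB (0.69), VLDLR and WARS1 were higher, and SLC7A11 and SLC3A2, which form the cystine transporter, were lower, with 9 higher and 2 lower adjusted over the list alone. In the spline test ASNS, CHAC1, TRIB3 and CEBPB rose, and adjusted over the list alone 10 rose and 2 fell.

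Cholesterol synthesis genes had a median of 0.18 in the late window against the unstimulated array over 16 members (adjusted p = 0.0084; adjusted p = 0.905 with an estimated correlation), with 0 past the limma threshold, 3 adjusted over the list alone and 6 with an unadjusted p under 0.05. From the early to the late window the median was 0.36 (adjusted p = 0.0012; adjusted p = 0.905 with an estimated correlation). The lanosterol synthase LSS (0.66, SE 0.14), the reductase DHCR7 (0.50, SE 0.09) and FDPS (0.56) were among 7 members that were higher, 9 did not pass, and adjusted over the list alone 10 were higher and 1 lower. Along the fitted curve 5 members rose, and adjusted over the list alone 6 rose and 1 fell.

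The late against the early window compared stimulated arrays alone, 3 against 3, and asked which genes differed between the start and the end of the course. NUP43 was 1.89 higher (SE 0.13, adjusted p = 1.8e-07), back at 8.64 ± 0.14 (SD, n = 3) from its low early level. ELOVL6, an elongase of fatty acids, was 1.29 higher (SE 0.16) and CDKN1A 1.38 higher (SE 0.25), or 0.95 without the 39 h array. PHEX was lower by -2.02 (SE 0.19, adjusted p = 1.9e-06), RPS6KA5 by -1.88 (SE 0.17, adjusted p = 1.5e-06), GCLM by -1.63 (SE 0.22) and the matricellular protein CCN3 by -1.47 (SE 0.17). GDPD1 (1.66), MOSPD2 (1.62), the metalloreductase STEAP2 (1.56), RFTN2 (1.43) and PREPL (1.31) were also higher, and SLAIN1 (-1.99), OR7A5 (-1.65), the glycosyltransferase GCNT2 (-1.62) and CCDC171 (-1.45) also lower. In all, 1602 genes passed, 666 higher and 936 lower, with 32 higher and 70 lower by more than 2-fold, and 3896 had an unadjusted p under 0.05. All 16 named genes passed whichever array was left out. The step of 199 genes between 11 and 15 h falls between these windows, and CIRBP (-1.17) and RBM3 (-0.55), chosen after values were seen, were lower with it. The count was 23 with all 3 windows shifted, which also put the 11 h array with the 15 and 19 h arrays, and 836 when a linear trend replaced the windows. It was 960 without the 11 h array, and 1314 without the 39 h array, of which 658 were higher and 656 lower.

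Further lists differed between the early and the late window. p53 targets had a median of 0.22 over 17 members (adjusted p = 0.011; adjusted p = 0.905 with an estimated correlation), with CDKN1A, SESN1 (0.66) and the DNA damage sensor XPC (0.53) higher and 6 adjusted over the list alone. In the 39 h array 15 of these 17 members were above their mean of 27 and 33 h, and without it the median was 0.12. Against the unstimulated array the median of the p53 targets was -0.14 in the early and 0.06 in the late window. MAPK output genes had a median of 0.31 over 17 members (adjusted p = 0.0247; adjusted p = 0.905 with an estimated correlation), with 6 higher, among them ETV5 (0.50) and IER3 (0.49), and 8 higher and 2 lower adjusted over the list alone. The call ended without the 11 h array (median 0.22, adjusted p = 0.112) or the 39 h array (median 0.18, adjusted p = 0.172). Against the unstimulated array the median of the MAPK output genes was -0.22 in the early and 0.03 in the late window. The difference between the windows thus lay mostly in low early values. Oxidative phosphorylation genes had a median of -0.13 over 24 members (adjusted p = 0.012; adjusted p = 0.962 with an estimated correlation), with the complex I subunit NDUFV2 (-0.60) and the complex IV subunit COX6C (-0.51) lower. That list rested on the 39 h array, where 23 of 24 members were below their mean of 27 and 33 h: without it the median was -0.00 (adjusted p = 0.636), and after quantile normalization the adjusted p was 0.107. It was -0.25 without the 27 h array. In the spline test 8 of its members fell over all genes and 9 adjusted over the list alone, 1 p53 target rose, and 1 MAPK output gene rose and 4 fell, with 1 and 10 past adjusted over those lists alone.

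Genes for pigment showed no list call in any window. Over 20 members the median from the early to the late window was -0.09 (adjusted p = 0.43). Tyrosinase, encoded by TYR and limiting for melanin synthesis, was 0.42 higher in the late than in the early window (SE 0.09, adjusted p = 0.0047), with 9.99 at 0 h, 9.91 ± 0.07 (SD, n = 3) early, 10.32 ± 0.11 in the middle and 10.33 ± 0.03 late, and the melanosomal exchanger SLC24A5 was 0.38 higher. RAB32 (-0.60) and RAB27A (-0.52), which act in melanosome traffic, HPS4 (-0.46) and the transporter SLC45A2 (-0.36) were lower. Over the whole course OCA2 (0.46) rose, RAB27A (-0.75) and RAB32 (-0.61) fell and 17 did not pass, and adjusted over the list alone 4 rose and 5 fell. In the 39 h array 18 of the 20 members were below their mean of 27 and 33 h. Among 15 melanocyte transcription factors 0 passed the limma spline test, 1 passed adjusted over the list alone and 5 had an unadjusted p under 0.05, and LEF1 was higher and ZEB2 and ETV1 lower in the late than in the early window. Of 20 MITF targets outside pigmentation CDKN1A and the desaturase SCD (0.67) rose, CEACAM1 (-0.64) fell and 17 did not pass, with 3 past adjusted over the list alone.

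The rhythm test asked for cycles of 24 h, since forskolin is known to set the clock of cultured cells. It called 0 of 17687 genes with limma, and 1326 had an unadjusted p under 0.05. The high recovery in the simulated data does not carry over to this count. In the data NR4A2, with a fitted amplitude of 0.79 (adjusted p = 0.376), and CCNE2, with 0.78 (adjusted p = 0.240), did not pass the rhythm test. Without the 39 h array 102 genes passed, and with a period of 28 h 140 did. Of the 18 measured clock genes none passed adjusted over the list alone (smallest adjusted p = 0.238), and 2, NR1D2 and NFIL3, had an unadjusted p under 0.05. In the spline test BHLHE40 (1.19 at 39 h), PER3 (0.62) and NPAS2 (0.39) rose, CRY1 (-0.63) fell and 14 did not pass, with 6 past adjusted over the list alone. Adjusted over each list alone, the 24 h term passed in 15 of 21 DNA replication, 11 of 13 heat shock and 7 of 21 mitosis genes, and in 1 gene each of the CREB, oxidative stress, p53 and melanocyte transcription factor lists. The stimulated arrays span 35 h, too short for a full second cycle. A single trough or step can therefore fit the 24 h term, and these counts do not show a repeated rhythm.

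The remaining lists had no camera call in any window. In the spline test 2 of 18 hypoxia genes passed, the oxygen sensor EGLN1, which rose, and the glycolytic ENO1, which fell, and 4 adjusted over the list alone. Of 17 lysosomal genes TPP1 (0.90) and CTSL (0.62) rose and CTSB (-0.59) fell, with 7 past adjusted over the list alone. Of 17 inflammatory genes IER3, TNFAIP3 and ICAM1 rose and PTGS2 fell, with 5 adjusted over the list alone, and at 39 h 14 of the 17 were above their mean of 27 and 33 h. Of 19 interferon genes OAS1 rose, of 20 ribosomal protein genes RPS6 fell and of 11 reference genes B2M (-0.59 at 39 h, adjusted p = 0.0431) fell, with 2, 3 and 1 past adjusted over the list alone. Of 19 DNA repair genes, 15 ER chaperones, 18 genes of dedifferentiation and invasion, 11 keratinocyte, 11 fibroblast and 14 immune and endothelial markers 0 passed the limma spline test over all genes or adjusted over the list alone. In these 6 lists 6, 2, 4, 0, 0 and 0 members had an unadjusted p under 0.05. Among the 1868 probe sets without a symbol 79 passed the spline test and 155 differed between the late and the early window.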

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

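The tests of the step between 11 and 15 h (the position of the 15 h array, the CREB list and the cold-inducible genes), of the 39 h array, and of signal loss, drift and order in the replication and mitosis genes were chosen after the results were seen, and the test of dim genes and the shuffled orders were planned.

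The 39 h array stood far from the others in 2 measures. The standard deviation of its log2 values was 1.99, with the nearest array at 2.04, and its median correlation with the other arrays was 0.981, with the nearest at 0.986. For each measure the gap to the next array was large against the whole range of the 10 arrays (0.527 and 0.540 of it). Both gaps were past a threshold that chance alone passes in about 1 in 20 sets of arrays for a single measure. Several measures were screened, and both flagged measures concern the same array.

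The first pattern weighed is the 39 h array itself, in which 55 genes were more than 2-fold below and 28 more than 2-fold above their mean of 27 and 33 h. A compressed signal range would be removed by a trend on signal level, and after that removal the spread of the array was still 1.28 times the median of the earlier arrays, a value the highest earlier array matched, so a compressed range stays open. RNA from other cell types would raise their markers together: the median of the keratinocyte markers was 0.227 higher at 39 h, that of the fibroblast markers 0.173 and that of the immune and endothelial markers 0.129, with 8 of 11, 8 of 11 and 10 of 14 members higher, and as these markers are dim, RNA from other cells and compression cannot be told apart here. A late biological response may also be part of it, since 15 of 17 p53 targets, CDKN1A among them, were higher. The shift was not particular to that list: 19 of 21 mitosis genes were higher too, and 23 of 24 oxidative phosphorylation genes lower. With 1 array a biological response cannot be separated from the handling of 1 culture.

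The second pattern is the step between 11 and 15 h, at which 199 genes differed more than 2-fold. Steady drift would put the 15 h array at 0.299 of the way from the early to the late mean. Over the genes that differed between those windows it lay at 0.701 (quartiles 0.411 and 1.05). The window test favours genes that stay level within a window, so this position does not decide how much of the change was drift. On the same scale the 0 h array lay at 0.469 (quartiles 0.173 and 0.722), where drift would give -0.286. For these genes the early arrays thus lay apart from the 0 h array as well as from the later ones. A technical batch of the 4, 7 and 11 h arrays is not excluded for the calls as a whole. Dim genes were called in 1.91% and the others in 13.8% of cases, a ratio of 0.138. For the CREB list a batch stays open too. Its median from the early to the late window lay at percentile 0.010 among random lists. Camera with the correlation estimated gave an adjusted p of 0.119, and the estimated correlation of this list was -0.0071. Correlation between members thus does not account for that higher adjusted p. As the camera test with the estimate did not pass, the list does not decide. A difference in culture temperature or handling may have contributed: RBM3 fell by 0.47 between the early and the middle window and CIRBP fell by 1.74, with no overlap between the windows, while the heat shock list went from a median of -0.34 to 0.24 against the 0 h array. Because each window was sampled in a single run of hours, temperature, a daily rhythm of these genes and a delayed effect of forskolin all remain open for the genes that moved with the step.

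The third pattern is the low level of replication and then of mitosis genes. The median of the reference genes in the middle window was -0.029 against -0.80 for the replication genes, so the replication genes were low relative to them. This cannot test an array-wide loss of signal, which the quantile normalization of RMA would largely have removed beforehand. A steady decline after serum depletion would keep a list falling from window to window. The replication genes were instead 0.449 higher in the late than in the middle window (21 of 21 members, and 0.534 without the 39 h array). Even so, their median went from -0.23 at 33 h to -0.48 at 39 h. The mitosis genes were at -0.497 between these windows, but their median went from -0.96 at 27 h to -0.59 at 33 h and -0.48 at 39 h. That return is counted from their lowest array, so for the mitosis genes the values do not decide. The replication genes were lowest at 17.5 ± 5.44 h and the mitosis genes at 28.2 ± 3.43 h (SD over 21 members each), a difference of 10.8 h, or 11.6 h without the 39 h array. That order had been read from the list medians first and comes from correlated members of 1 time course, so it does not decide whether cells moving through the cycle in step lie behind it, and neither counts of cells per phase nor a course without forskolin, which would decide it, was analysed here.

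The real order of the times gave 861 genes in the spline test, and the highest of 100 random orders gave 35. For the late against the early window the real grouping gave 1602 genes and the highest of 100 others 951. That other grouping also kept the 4, 7 and 11 h arrays together, against the 15, 19 and 33 h arrays. Its count thus points to the same step after 11 h. Both results show that the arrays were not interchangeable in time. Neighbouring arrays of a time course can be alike through a batch or handling, and no time point has a replicate. These counts therefore do not exclude variation between single cultures. For the rhythm chance cannot be excluded: at an unadjusted p under 0.05 the real order gave 1326 genes, and 18 of 101 orders, the real one included, gave as many or more, up to 3711.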

How the results depend on the processing

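List tests after quantile normalization or median centring and the shifted middle window were added after the results were seen, and all other alternatives were planned. Among the tests of named genes under the alternatives, 3689 kept their direction and side of the threshold, 373 lost and 24 gained a call, and 1 reversed: GDPD1, at -1.09 with a curve of 4 degrees of freedom against 1.46, whose largest departure moved to another time. Without the trend on mean signal the spline test gave 375 genes, the early and middle windows against the unstimulated array 25 each and the late window 5. With the dimmest 40% left out, and so fewer genes tested, the late window against the unstimulated array gave 83. The spline test gave 2271 genes with 4 degrees of freedom, 496 with linear time and 1302 on the 9 stimulated arrays. The late against the early window gave 836 as a linear trend, and all 9 stimulated arrays against the unstimulated one gave 4. Shifted windows, which put the 11 h array with the 15 and 19 h arrays, gave by limma 0 genes for the early (829 at an unadjusted p under 0.05), 7 for the middle and 4 for the late window against the unstimulated array, and 23 for late against early. A rhythm of 28 h gave 140 genes. Of 21 list calls 0 held with camera and an estimated correlation, 8 held with fry, which tests lists against no change rather than against other genes and made 9 calls, and 20 held under quantile normalization and 21 under median centring. Leaving out each array in turn gave 222 to 1454 genes for the spline test, 52 to 170 for the early, 42 to 210 for the middle and 29 to 80 for the late window against the unstimulated array, 960 to 1697 for late against early, 0 to 102 for the rhythm and 19 to 23 list calls. The unstimulated array could not be left out of its own comparisons, and the list calls were counted with it in place. The counts against the unstimulated array were highest without the 39 h array. The late window against the unstimulated array had 36 higher and 32 lower genes after quantile normalization and 10 and 29 after median centring, against 18 and 30, and late against early 519 and 1164 after median centring, against 666 and 936. Apart from the fewer genes tested and the shifted windows, the cause was not tested. No paired analysis was possible because each time point has 1 array. Dim genes lie near the background of the arrays, where a change is harder to see.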

Other observations

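The genes in this part were chosen after their values were seen, and no test was added for them.

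Of 64 measured histone genes of the gene clusters, which were not tested as a group, 58 had a lower value in the middle window than in the unstimulated array, and the 6 given here were the genes that passed the threshold. H2AC11 was -1.06 (adjusted p = 0.0157), H4C8 -0.99 (adjusted p = 0.019), H2AC8 -0.91 (adjusted p = 0.0251), with H3C1 (adjusted p = 0.0322) and H2BC5 (adjusted p = 0.0464) at 5.28 ± 0.16 and 6.02 ± 0.22 (SD, n = 3) against 6.47 and 7.02 at 0 h, and H2BC12 -0.73 (adjusted p = 0.00482). Single genes were lower in the early window. ERBB3, a receptor of neuregulin that is strong in pigment cells, was -1.22 from the unstimulated array (SE 0.19, adjusted p = 0.00404) and 8.60 ± 0.25 (SD, n = 3) against 9.81. The retinoic acid receptor gene RARG was at 6.25 at 0 h, 5.20 ± 0.28 early, 6.48 ± 0.02 in the middle and 6.38 ± 0.10 late. LEF1 was 0.86 higher in the late than in the early window, and PTCH1 was at 8.99 at 0 h, 7.65 ± 0.21 early and 8.85 late, so both moved back towards their unstimulated levels.

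Levels in the early and later windows lay apart for the following genes. NUP43 was at 6.75 ± 0.05 (SD, n = 3) in the early and 8.75 ± 0.23 in the middle window, MOSPD2 at 7.51 ± 0.09 and 9.07 ± 0.26, PREPL at 7.99 ± 0.09 in the early and 9.31 ± 0.07 in the late window, and the iron reductase CYBRD1 at 8.53 ± 0.10 early and 9.63 ± 0.08 in the middle. In the other direction, LANCL2 was at 9.36 ± 0.15 early and 7.92 ± 0.12 in the middle, and CCDC171 at 10.39 ± 0.06 and 9.09 ± 0.10. NAMPT, which makes the NAD precursor nicotinamide mononucleotide, was -0.84 in the late against the early window (SE 0.11, adjusted p = 8.5e-05), and the cyclic AMP phosphodiesterase PDE3A was -0.68 (SE 0.10, adjusted p = 0.0002). LINC00473, a transcript known to be induced by cyclic AMP, was 0.94 higher in the early window than at 0 h (SE 0.19, adjusted p = 0.0241).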
